A study of Mus musculus with 12 samples.

How the data were processed

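RNA of C57BL/6 mice, a common inbred laboratory strain, was sequenced in 12 samples that form 6 groups of 2: sperm DNA-associated RNA, sperm free RNA and testis DNA-associated RNA, each at 6 and 14 months of age. Per the labels' protocols, sperm came from the cauda epididymis and were extracted with TRIzol, a phenol reagent that parts RNA in a watery upper phase from DNA in the layer beneath it. Free RNA was taken from the watery phase, and the RNA that stayed with the DNA was recovered from the interphase. Both were treated with proteinase K, purified on columns and sequenced on a HiSeq or MiSeq instrument, per the labels' protocols.

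The authors deposited quantification tables with 1 line per transcript. Per the file headers they hold estimated counts, that is expected numbers of reads that need not be whole, and TPM, levels scaled for transcript length and library size, both computed by the authors, beside transcript lengths and effective lengths. The layout is that of Salmon output, and the submitters' processing notes name Salmon 0.12.0, FastQC 0.11.5, Trimmomatic 0.36, HOMER 4.9, HISAT2, featureCounts, Bowtie2, DESeq2 and edgeR, and the builds GRCm38 and mm10, without saying what each was used for. Salmon divides reads that match several transcripts between them, so values of near-identical copies are uncertain. Whether counting used strand is not given in the sources used here, so genes with an antisense partner are uncertain too. A further deposited file lists chromosome ends as positions and sequences in mm10 and holds no value of any sample, so no telomeric repeat RNA level could be computed from it.

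There were 8 quantification tables. Each sperm group had 1, and its name does not say whether it holds rep1, rep2 or both. Each testis group had 2, marked L001 and L002. Over genes with at least 20 reads, the median chi-square of L001 against L002 was 1.04 times its chance value at 6 months and 1.08 times at 14 months, and 6.48% and 6.65% of genes had an unadjusted p under 0.05. Between ages the same ratio was 1.90 in sperm DNA-associated, 5.20 in testis and 76.2 in sperm free RNA. L001 and L002 were therefore summed, which gave 1 library per group and 6 in all. Nothing says which animals the libraries came from, so differences between these libraries may be technical. With 1 library per group, the 2 ages served as the replicates of each kind of RNA. The p-values therefore rest on how far the age difference of a gene varies between the kinds of RNA. An age difference in 1 kind alone counts as spread, and spread between replicates of a group is not measured.

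Estimated counts were summed per gene for 134961 transcripts of 53090 genes. Emptied lines of 6 transcripts were left out, and those transcripts, and some genes that the rules below select, are not reported here. Gene names were those paired with GENCODE identifiers in the tables, and 112 gene identifiers that share a symbol were kept apart by their identifier. Of the gene identifiers, 24863 matched a RefSeq symbol of assembly GRCm38.p6 (19091 of the 21811 protein-coding genes), and positions are those of that annotation, counted from 1. Levels are given as CPM, the counts of a gene scaled to a common library total. Fold changes come from the model and use TMM scaling, so they can differ from ratios of CPM. TMM factors were 1.66 and 1.51 for sperm DNA-associated, 1.34 and 0.511 for sperm free and 0.781 and 0.747 for testis DNA-associated RNA at 6 and 14 months.

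Counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): a quasi-likelihood fit over all 6 libraries with a term for the kind of RNA and a term for age, on the 34355 genes with at least 1 CPM in at least 2 libraries. The fit left 2 residual degrees of freedom, with a common dispersion of 0.21 and a median prior of 6.08 degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, called the edgeR adjusted p in the text. SE, an approximate standard error, is the absolute log2 fold change over the square root of the F statistic of its test. The contrasts tested were sperm DNA-associated against free RNA, testis against sperm DNA-associated RNA, and 14 against 6 months over the kinds of RNA. Age within a kind of RNA has 1 library per age and no test. There, the log2 ratio used a pseudocount of 1 CPM, and counts are of genes with at least a 2-fold difference and 10 CPM after TMM scaling in the higher library. Intervals of shares are 95% Wilson intervals, and those of log2 ratios between single libraries are 95% counting intervals. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 counts over the group, from CPM. All intervals and floors cover counting error only.

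Counts were also simulated with the real library sizes, giving every library the same level per gene, its mean over the 6 libraries. Among 34355 genes, 100 were changed by each of 2 sizes, all with a mean over 10 CPM. The test recovered 0% of changes of log2 1 in each contrast. Of changes of log2 3 it recovered 36% for sperm DNA-associated against free RNA, 41% for testis against sperm DNA-associated RNA and 87% for age. It called 2, 5 and 8 unchanged genes in these contrasts. The real differences between the kinds of RNA were thus absent. Far fewer genes were changed than passed in the fraction and tissue comparisons of the data. The rates therefore do not give the power of these contrasts in the data.

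Of 18 gene lists written down before the data were examined, 17 had measured members: late spermatid, meiotic spermatocyte, spermatogonia, Sertoli, Leydig, peritubular and endothelial, epididymal epithelium, blood and immune, mitochondrially encoded, nuclear long non-coding RNA, non-coding RNA machinery, R-loop processing, telomere maintenance, senescence and inflammation, imprinted, long neuronal and ubiquitous genes. The list of repeat families had 0 measured members. Of the 30 names of the non-coding RNA machinery list, 19 were in the tables. Lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 17 lists of each contrast. Of the 51 list tests, 31 passed with the preset correlation, 0 with an estimated correlation and 28 with library totals in place of TMM. The estimated correlation rests on the 2 residual degrees of freedom of the fit, so it is itself uncertain and neither setting settles a list. Within a kind of RNA, a list's median was placed among 10000 random lists matched on level.

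Genes were named by a rule also set before the data were examined: for each contrast the 10 largest changes per direction among passing genes with both ages moving the same way and a mean of at least 10 CPM in the higher group, or, where fewer passed, the 10 with the largest smaller-of-both-ages change. The direction at each age, or in each kind of RNA, was judged on CPM from library totals. Predicted models and pseudogenes were counted and not named. Up to 4 members of each list with the highest levels were added, of which the text gives 1 to 4 per list. Exceptions are marked where they occur.

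The contrasts, tests, gene lists, naming rule and most alternatives were set before the data were examined. Alternatives were DESeq2 size factors, library totals without TMM, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of 5 CPM, no age term, only the groups compared, each table as its own library, transcripts in place of genes, leaving out mitochondrial, ribosomal, 7SK and 7SL RNA genes, and leaving out each library. Leaving out 10 satellite-related gene models was added after seeing the data, as was the list of those models. Numbers of detected genes were recomputed at 5 CPM and after thinning to 7790098 reads per library. Files were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.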

Results

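RNA that stays with DNA was compared with freely soluble RNA in mouse sperm, and with DNA-associated RNA of the testis, at 6 and 14 months of age. The series concerns DNA-RNA hybrids, in which an RNA strand pairs with DNA, from telomeres to the rest of the genome. The 12 samples form 6 groups of 2, and the tables used here give 1 library per group. The 2 tables of each testis group differed by about the sampling noise and were counted as 1 library. Estimated reads at 6 and 14 months were 7790377 and 15624498 in sperm DNA-associated RNA, 23194789 and 31030747 in sperm free RNA, and 34140988 and 46236168 in testis DNA-associated RNA. A gene at 10 CPM rested on 78 reads in the shallowest library, with a 95% Wilson interval of 8.02 to 12.5 CPM, and on 462 reads in the deepest, with an interval of 9.12 to 10.9 CPM. A count of 0 allows up to 0.385 CPM in the former and 0.065 CPM in the latter.

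The sperm DNA-associated libraries were dominated by 10 predicted gene models related to pericentromeric satellite repeats, a set put together after the values were seen. These models took 50.4% of the reads at 6 months (95% Wilson interval 50.4 to 50.47) and 48.6% at 14 months (48.58 to 48.63). They took 5.31% (5.301 to 5.319) and 0.0405% (0.03979 to 0.04121) of sperm free RNA, and 2.24% (2.23 to 2.24) and 0.711% (0.7089 to 0.7138) of testis DNA-associated RNA. Gm10800 alone made up 31.4% and 30.8% of the sperm DNA-associated reads. Rn7s1, the 7SL RNA of the signal recognition particle, was lowest in sperm DNA-associated RNA: 0.0218% and 0.143% of sperm DNA-associated reads, 4.36% and 7.31% of sperm free reads and 1.93% and 1.64% of testis reads. Mitochondrial genes made up 0.189% and 0.468% of sperm DNA-associated, 5.34% and 1.41% of sperm free, and 0.294% and 0.566% of testis DNA-associated reads.

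**Figure D1:**
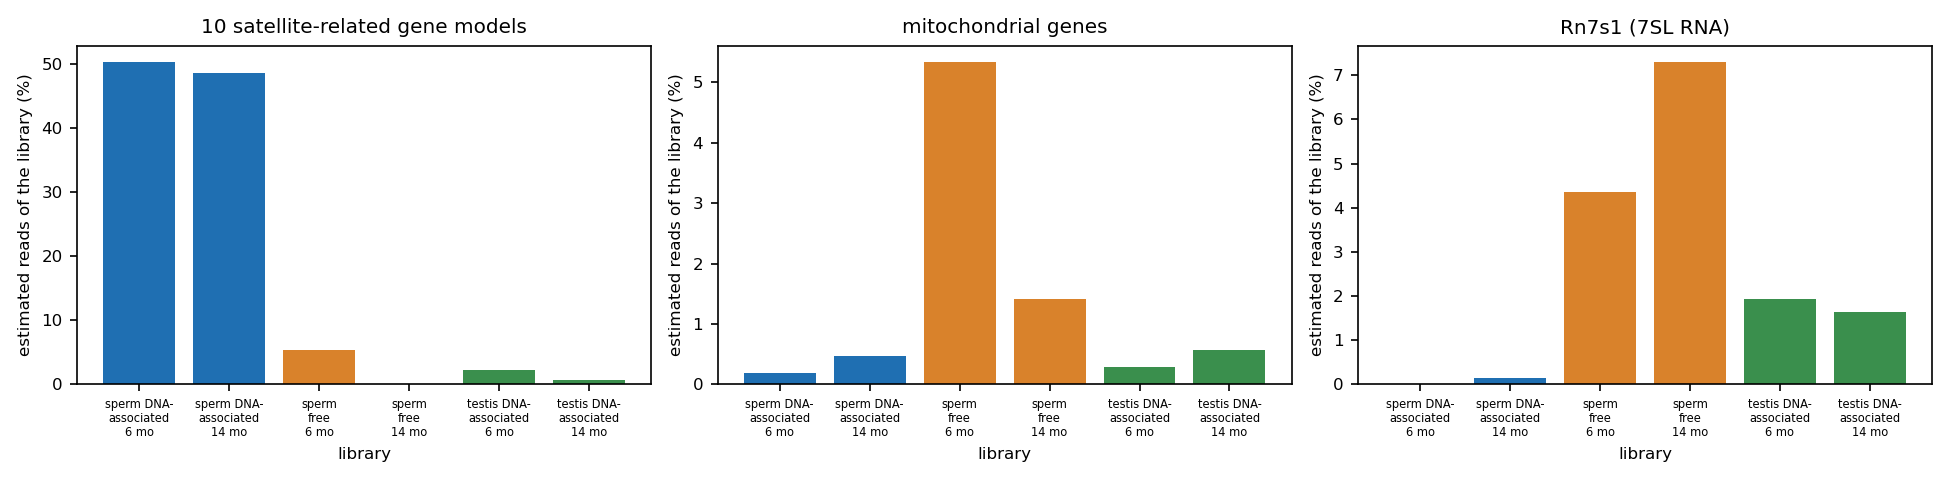
Share of the estimated reads of each library (percent, axis from 0) taken by 10 satellite-related gene models, mitochondrial genes and Rn7s1, with 1 bar per library. The satellite-related models take 50.4% and 48.6% of the sperm DNA-associated libraries and at most 5.31% of the others.

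More genes reached 1 CPM in sperm DNA-associated RNA than in the other kinds: 35022 and 34224 genes, against 29428 and 20937 in sperm free RNA and 21744 and 21200 in testis DNA-associated RNA. Thinned to 7790098 reads, the means per kind were 34828, 25470 and 21665 genes. At 5 CPM the order turned for the 6-month sperm free library, with 17915 genes against 17108 and 17559 in the sperm DNA-associated libraries. Across the tested genes, which are not independent replicates, log levels correlated with a Pearson's r of 0.96 between the sperm DNA-associated libraries, 0.99 between the testis libraries and 0.87 between the sperm free libraries. The 14-month sperm free library correlated at 0.91 with each testis library and the 6-month one at 0.84 and 0.83. With the sperm DNA-associated libraries the 6-month one correlated at 0.72 and 0.78 and the 14-month one at 0.41 and 0.51. The scaling sets where 0 lies: the median log2 fold change of all genes for sperm DNA-associated against free RNA was -0.08 with TMM, 0.35 with DESeq2 size factors and 0.81 with library totals. For testis against sperm DNA-associated RNA it was -0.48, -0.62 and -1.53, and for age 0.08, -0.05 and -0.45.

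The first comparison sets DNA-associated against free RNA of the sperm preparations. In the DNA-associated libraries, reads from genomic DNA cannot be told apart from RNA, as described further below. The free libraries also hold markers of somatic cells. A fall or rise is therefore a difference between libraries, and is not shown to be a split of sperm transcripts. Transcripts of late spermatogenesis were scarce in the DNA-associated fraction: all 54 late spermatid genes fell against free RNA, with a median log2 fold change of -5.54 (SD over genes 1.00). Prm2, a protamine that packs sperm DNA, stood at 10.4 and 99.7 CPM in DNA-associated RNA at 6 and 14 months and at 1156 and 4598 CPM in free RNA. Of 16 genes of the non-coding RNA machinery 13 were also lower in the DNA-associated fraction, as were the nuclear RNAs Malat1, by 84.3-fold, and Neat1. Among the fewer genes that rose were Xkrx, a gene of the XK membrane protein family, at 10280 and 7148 CPM against 1142 and 32.5 CPM, and Apol7e, of the apolipoprotein L family, at 19.9 and 25.9 CPM against 1.62 and 0.644 CPM.

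By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9366 of 34355 genes fell and 718 rose in sperm DNA-associated against free RNA. Protein-coding genes gave 8183 that fell and 416 that rose of 20551, and the other biotypes 1183 and 302 of 13804. The share of calls that were higher, 7.1%, was 18.9% with DESeq2 size factors, 1.7% with library totals (5482 calls), 29.1% with the stricter filter and 33.6% by the DESeq2 test. Without the 14-month DNA-associated library 181 genes passed, and without the 6-month one 1782, while without the 6-month free library 24426 passed, 54.7% of them higher.

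Of the late spermatid genes, all 54 also fell when adjusted over the list alone. Prm2 (ENSMUSG00000038015.6, chromosome 16, 10791377 to 10792105) had a log2 fold change of -7.08 (SE 1.68, edgeR adjusted p = 0.016). Its neighbour Tnp2, a transition protein that precedes protamines on DNA, had -6.96 (SE 1.58, edgeR adjusted p = 0.014). Tnp1, the other transition protein, was 163-fold lower, Odf2 of the sperm tail's outer dense fibres 61.8-fold, and Tcp11 95.4-fold. Of the 37 meiotic spermatocyte genes 24 fell and 13 did not pass (25 fell adjusted over the list alone). Hspa2, a testis chaperone, was 54.6-fold lower and Stag3, a meiotic cohesin subunit, 16.6-fold lower. Of the 24 spermatogonial genes 9 fell, 2 rose and 13 did not pass, with the same counts adjusted over the list alone. Ddx4, a germ-cell RNA helicase, was 18.1-fold lower and Tex101 7.27-fold lower. That list's median was -0.93 with TMM and 0.02 with library totals, so its direction depends on the scaling.

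Among markers of somatic cells, part of each list was lower. Of 33 epididymal epithelium genes 28 fell and 5 did not pass (29 fell adjusted over the list alone; median log2 fold change -4.27). Gpx5, a secreted glutathione peroxidase of the epididymis, stood at 445 and 911.1 CPM in free RNA and at 5.78 and 44.7 CPM in DNA-associated RNA (log2 fold change -6.11, SE 1.23, edgeR adjusted p = 0.01). The protease-family genes Adam7 and Adam28 were 67.4-fold and 19.3-fold lower, and the lipocalin Lcn8 83.1-fold. Of 24 blood and immune genes 14 fell and 10 did not pass (15 fell adjusted over the list alone). The haemoglobin genes Hba-a2 and Hbb-bs were 92.9-fold and 77.1-fold lower, with the limit that Hba-a2 shares reads with a near-identical copy. Of 24 Sertoli genes 16 fell and 8 did not pass (19 fell adjusted over the list alone), among them Clu, the chaperone clusterin, 64.8-fold lower, and Amhr2, a receptor of anti-Müllerian hormone, 12.3-fold lower. Of 14 Leydig genes 9 fell and 5 did not pass, as they did adjusted over the list alone. Insl3, a hormone of Leydig cells, was 52.4-fold lower, and the lipoprotein receptor Scarb1 5.68-fold lower. Of 17 peritubular and endothelial genes 9 fell and 8 did not pass, also adjusted over the list alone, with Actg2, a smooth-muscle actin, 38.4-fold and the collagen Col3a1 20.0-fold lower.

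Genes of the non-coding RNA machinery showed the lowest median of all lists, -6.58. Of 16 tested genes 13 fell and 3 did not pass (15 fell adjusted over the list alone). Rnu1a1, a U1 RNA of the spliceosome, was 246-fold lower (log2 fold change -7.94, SE 1.31, edgeR adjusted p = 0.0094), and Rn7sk, the 7SK RNA that restrains transcription elongation, 155-fold lower. Rn7s1 (log2 fold change -7.48, SE 2.54) and the ribosomal Rn18s-rs5 (-5.14, SE 1.74) did not pass, each with an edgeR adjusted p of 0.058. Of the 29 nuclear long non-coding RNAs 9 fell, 0 rose and 20 did not pass, with the same counts adjusted over the list alone. Malat1 (chromosome 19, 5795690 to 5802672) had a log2 fold change of -6.40 (SE 1.35, edgeR adjusted p = 0.011) and Neat1, the RNA of paraspeckles, -5.37 (SE 1.07, edgeR adjusted p = 0.01). Kcnq1ot1, an antisense RNA of an imprinted domain, had 0.36 (SE 0.84, edgeR adjusted p = 0.74), and Snhg14, a host of small nucleolar RNAs, 2.54 (SE 0.92, edgeR adjusted p = 0.073). The list's median was 0.05, its mean -0.55, and camera gave it the direction down with an adjusted p of 0.731.

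Of 15 mitochondrially encoded genes 7 fell and 8 did not pass (9 fell adjusted over the list alone). The ribosomal RNAs mt-Rnr2 and mt-Rnr1 were 97.1-fold and 78.6-fold lower, though mt-Rnr2 passed neither with library totals nor with the stricter filter. Of the 20 ubiquitous genes 19 fell and 1 did not pass, also adjusted over the list alone. The elongation factor gene Eef2 was 50.3-fold lower. Of 27 genes that process R-loops 18 fell, 1 rose and 8 did not pass (20 fell and 1 rose adjusted over the list alone), with Rnaseh2a, a subunit of ribonuclease H2, 32.4-fold lower. Of 24 telomere maintenance genes 13 fell and 11 did not pass (14 fell adjusted over the list alone). Daxx, a histone chaperone, had a log2 fold change of -3.70 and Rif1 was 9.17-fold lower, whereas Pot1b, which binds single-stranded telomeric DNA, stood at 333.1 and 297 CPM against 204.4 and 24.8 CPM and did not pass (log2 fold change 1.17, SE 0.67, edgeR adjusted p = 0.2). Smchd1, a chromatin protein, had -0.23 (SE 0.48, edgeR adjusted p = 0.7) and 0.63 with library totals.

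Of 22 senescence and inflammation genes 8 fell and 14 did not pass, with the same counts adjusted over the list alone. Bcl2l1, an inhibitor of apoptosis, was 14.6-fold lower, and the protease Mmp12, at 75.2 and 64.2 CPM against 43.6 and 2.51 CPM, did not pass (edgeR adjusted p = 0.17). Of 29 imprinted genes 9 fell, 2 rose and 18 did not pass, again also adjusted over the list alone, with Gnas, a G protein subunit, 15.8-fold lower. Their median was -0.48 with TMM and 0.49 with library totals. Of 33 long neuronal genes 29 did not pass, 3 fell and 1 rose (2 fell and 0 rose adjusted over the list alone). Their median was 0.30, with Dpp10 at 1.43 (SE 0.76, edgeR adjusted p = 0.17) and Auts2 at -0.94 (SE 0.52, edgeR adjusted p = 0.18).

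With the preset correlation, camera placed 11 lists lower in sperm DNA-associated than in free RNA. They ran from late spermatid genes (camera adjusted p = 4.08e-26) to Leydig genes (camera adjusted p = 0.0317). None kept its call when the correlation was estimated: the adjusted p = 0.531 with an estimated correlation for late spermatid, Sertoli, epididymal, non-coding machinery, R-loop, telomere and ubiquitous genes, 0.491 for meiotic, 0.593 for mitochondrial, and 0.66 for Leydig and blood genes. The adjusted p with the preset correlation was 0.182 for spermatogonial, 0.0621 for peritubular and endothelial, 0.0541 for senescence, 0.731 for imprinted and 0.0668 for long neuronal genes. With library totals the same 11 lists passed, and long neuronal genes passed as higher (camera adjusted p = 0.0301), both with the preset correlation. With library totals and an estimated correlation no list passed in any of the 3 comparisons, and the lowest camera adjusted p was 0.428.

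The 10 largest falls by the naming rule include near-identical copies, whose values are uncertain. Hist2h2aa1, a histone H2A gene with a near-identical copy in Hist2h2aa2, had no whole read in either DNA-associated library and was at least 287.7-fold lower there. Fam205a3, also without a whole read there, was at least 204.9-fold lower. Rps27rt, a copy of a ribosomal protein gene, had 1 read in the DNA-associated libraries and 3647 in the free ones, a ratio of 1575 (counting interval 282.5 to 62220). Snord22, a small nucleolar RNA, had 3 and 1847 reads, a ratio of 265.8 (90.8 to 1290). Hist2h2aa2 stood at 0 and 0.674 CPM against 26.5 and 45.1 CPM. Ldhal6b, a lactate dehydrogenase-like gene, was 173-fold and Pgp, a phosphoglycolate phosphatase, 152-fold lower.

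The 10 largest rises were smaller than the falls. Apol7e (chromosome 15, 77695706 to 77719288) rose 11.7-fold (log2 fold change 3.54, SE 0.54, edgeR adjusted p = 0.0094). Xkrx (ENSMUSG00000031258.4, chromosome X, 134149037 to 134185497) rose 21.7-fold (SE of log2 1.40, edgeR adjusted p = 0.046) and Flg2, a filaggrin-family gene of skin, 22.3-fold (SE 1.39, edgeR adjusted p = 0.043). The transcription factor gene Zic4 rose 13.3-fold, the vomeronasal receptor gene Vmn2r30 12.4-fold, the cadherin gene Dchs2 10.7-fold, the oxidase gene Duox2 9.98-fold, the galactosyltransferase gene B3galt5 9.30-fold, the signalling regulator Rgs8 9.20-fold and Hkdc1, a hexokinase-like gene, 8.85-fold. With library totals only Apol7e passed (edgeR adjusted p = 0.01), and without the 14-month DNA-associated library none of the 10 did. Of the satellite-related models, with log2 fold changes of 4.98 to 6.01, Gm10722 alone passed (edgeR adjusted p = 0.049). Gm10800 had 5.44 (edgeR adjusted p = 0.19).

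**Figure D2:**
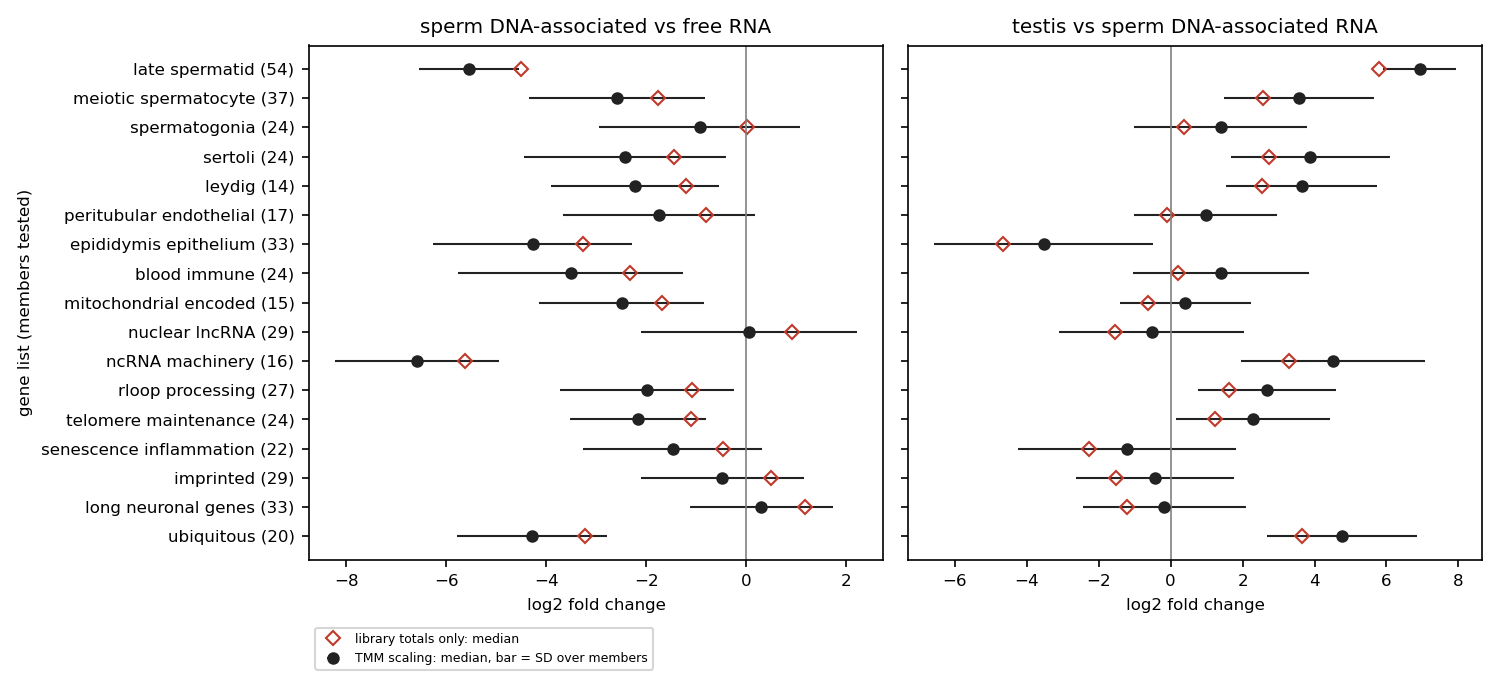
Median log2 fold change of each gene list for sperm DNA-associated against free RNA and for testis against sperm DNA-associated RNA. Filled points are medians with TMM scaling, bars the SD over list members and open diamonds medians with library totals. Late spermatid genes lie at -5.54 and 6.92, and spermatogonial, imprinted, peritubular and mitochondrial medians change sign between the scalings in 1 of the panels.

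The second comparison sets DNA-associated RNA of the testis, where sperm are formed, against that of sperm. Germ-cell transcripts were abundant in the testis fraction: all 54 late spermatid genes rose (median log2 fold change 6.92), and Prm2 stood at 4707 and 4900.0 CPM against 10.4 and 99.7 CPM in sperm. Among the other lists, 32 of 37 meiotic, 20 of 24 Sertoli, 12 of 14 Leydig, 19 of 20 ubiquitous and 24 of 27 R-loop processing genes rose. Epididymal epithelium genes went the other way, with 23 of 33 lower in testis, and Gpx5 stood at 0.352 and 0.151 CPM in testis. Malat1 was 41.1-fold higher in testis, and Snhg14 8.92-fold lower.

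By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11324 of 34355 genes were higher and 10971 lower in testis than in sperm DNA-associated RNA. Protein-coding genes were more often higher (9510 against 4925 lower), and other biotypes more often lower (6046 against 1814 higher). Calls that were higher made up 50.8%, and 63.5% with no filter and 69.6% over transcripts, against 38.2% without the 6-month sperm free library (28874 calls). Without the 14-month sperm DNA-associated library 5589 genes passed, without the 6-month one 14728, and without the 6-month and 14-month testis library 9851 and 12719.

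All 54 late spermatid genes also rose adjusted over the list alone. Prm2 had a log2 fold change of 8.58 (SE 1.84, edgeR adjusted p = 0.0059), Tnp2 8.41 (SE 1.74, edgeR adjusted p = 0.0051), Tcp11 8.15 (SE 1.57) and Odf2 7.95 (SE 1.56). Of 37 meiotic genes 32 rose and 5 did not pass (33 rose adjusted over the list alone), with Hspa2 245-fold and Stag3 80.0-fold higher. Of 24 spermatogonial genes 11 rose, 2 fell and 11 did not pass, also adjusted over the list alone, with Ddx4 74.3-fold and Tex101 70.1-fold higher. Of 24 Sertoli genes 20 rose and 4 did not pass, and of 14 Leydig genes 12 rose and 2 did not pass, both with the same counts adjusted over the list alone. Clu was 120-fold, Amhr2 99.0-fold, Insl3 301-fold and Scarb1 11.1-fold higher. Of 17 peritubular and endothelial genes 5 rose, 1 fell and 11 did not pass (4 rose and 1 fell adjusted over the list alone). Actg2 was 79.8-fold higher, and Col3a1 did not pass (log2 fold change 1.30, SE 0.72, edgeR adjusted p = 0.14). That list's median was 0.97 with TMM and -0.09 with library totals.

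Of 33 epididymal epithelium genes 23 fell, 4 rose and 6 did not pass in testis, with the same counts adjusted over the list alone and a median of -3.53. Lcn8 was 57.4-fold lower (log2 fold change -5.84, SE 0.92, edgeR adjusted p = 0.0022), Gpx5 28.2-fold, Adam7 23.9-fold and Adam28 6.54-fold. Of 24 blood and immune genes 5 rose, 4 fell and 15 did not pass (3 rose and 4 fell adjusted over the list alone). Hba-a2 had a log2 fold change of 2.01 (SE 1.36, edgeR adjusted p = 0.21) and Hbb-bs 2.51 (SE 1.34, edgeR adjusted p = 0.13). Of 15 mitochondrially encoded genes 1 fell and 14 did not pass, also adjusted over the list alone. The log2 fold change was 3.23 for mt-Rnr2 (SE 1.43, edgeR adjusted p = 0.074) and 2.98 for mt-Rnr1 (SE 1.18, edgeR adjusted p = 0.054), and the list's median of 0.41 became -0.63 with library totals.

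Of 16 non-coding RNA machinery genes 10 rose and 6 did not pass, also adjusted over the list alone. Rn7sk was 283-fold and Rnu1a1 98.6-fold higher in testis, while Rn7s1 had a log2 fold change of 6.18 (SE 2.46, edgeR adjusted p = 0.054) and Rn18s-rs5 -0.21 (SE 1.59, edgeR adjusted p = 0.91). Of 29 nuclear long non-coding RNAs 8 rose, 7 fell and 14 did not pass, with the same counts adjusted over the list alone. Malat1 had a log2 fold change of 5.36 (SE 1.30, edgeR adjusted p = 0.0096), Neat1 3.10 (SE 0.98, edgeR adjusted p = 0.025), Kcnq1ot1 -0.70 (SE 0.83, edgeR adjusted p = 0.46) and Snhg14 (chromosome 7, 59272737 to 60450177) -3.16 (SE 0.89, edgeR adjusted p = 0.017). Of 27 R-loop processing genes 24 rose and 3 did not pass, also adjusted over the list alone, with Rnaseh2a 125-fold higher. Of 24 telomere maintenance genes 14 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone. Daxx was 41.5-fold and Rif1 14.6-fold higher, Pot1b (chromosome 17, 55651190 to 55712647) was 7.45-fold lower (log2 fold change -2.90, SE 0.69, edgeR adjusted p = 0.009), and Smchd1 had -0.51 (SE 0.48, edgeR adjusted p = 0.36).

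Of the 20 ubiquitous genes 19 rose and 1 did not pass (20 rose adjusted over the list alone), with Eef2 115-fold higher. Of 22 senescence and inflammation genes 7 rose, 7 fell and 8 did not pass, also adjusted over the list alone, with Bcl2l1 43.7-fold higher and Mmp12 at a log2 fold change of -1.77 (SE 0.75, edgeR adjusted p = 0.065). Of 29 imprinted genes 10 rose, 7 fell and 12 did not pass, with the same counts adjusted over the list alone. Gnas was 13.3-fold higher. The list's median was -0.44, its mean 0.20, and camera gave it the direction up with an adjusted p of 0.89. Of 33 long neuronal genes 9 rose, 9 fell and 15 did not pass (9 rose and 8 fell adjusted over the list alone). Dpp10 fell by 1.88 on the log2 scale (SE 0.73, edgeR adjusted p = 0.0498), a call lost with library totals, and Auts2 had 0.39 (SE 0.51, edgeR adjusted p = 0.51), against -0.66 with library totals.

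With the preset correlation, camera placed 9 lists higher and the epididymal list lower in testis, from late spermatid (camera adjusted p = 7.56e-24) to spermatogonial genes (camera adjusted p = 0.0159), whose call was lost with library totals (camera adjusted p = 0.0987). None passed with an estimated correlation: the adjusted p = 0.27 with an estimated correlation for meiotic genes, 0.669 for epididymal genes and 0.658 for late spermatid, spermatogonial, Sertoli, Leydig, non-coding machinery, R-loop, telomere and ubiquitous genes. The preset adjusted p was 0.159 for peritubular and endothelial genes, 0.89 for imprinted genes and 0.716 for blood, mitochondrial, nuclear long non-coding, senescence and long neuronal genes.

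Of the 10 largest rises in testis, Ldhal6b rose 1136-fold, Dynlt1b, a dynein light chain gene, 691-fold, Ubb, a polyubiquitin gene, 533-fold, Fabp9, a fatty acid binding protein of sperm, 462-fold, Ldhc, the germ-cell lactate dehydrogenase, 448-fold, and Hist1h2ba, a testis H2B histone gene, 444-fold. Hist2h2aa1 was at least 505.8-fold and Fam205a3 at least 438.9-fold higher, Hist2h2aa2 stood at 128 and 87.3 CPM against 0 and 0.674 CPM, and Rps27rt had a ratio of 662.7 (counting interval 118.8 to 26190). These last genes have near-identical copies and are uncertain. Apol7e was the gene with the largest fall by the rule, with 3 reads in both testis libraries together and a ratio of 640.8 (counting interval 218.1 to 3117). The cornified-envelope gene Sprr2a1 was 194-fold lower, the major urinary protein gene Mup9 63.0-fold, the vomeronasal receptor genes Vmn2r96 and Vmn2r30 54.4-fold and 29.4-fold, Flg2 50.8-fold, the fucosyltransferase gene Fut9 43.2-fold, the cytochrome P450 gene Cyp3a41a 41.6-fold and the filaggrin-family gene Hrnr 31.6-fold. Mup9, Cyp3a41a and the vomeronasal genes belong to families whose members share sequence.

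**Figure D3:**
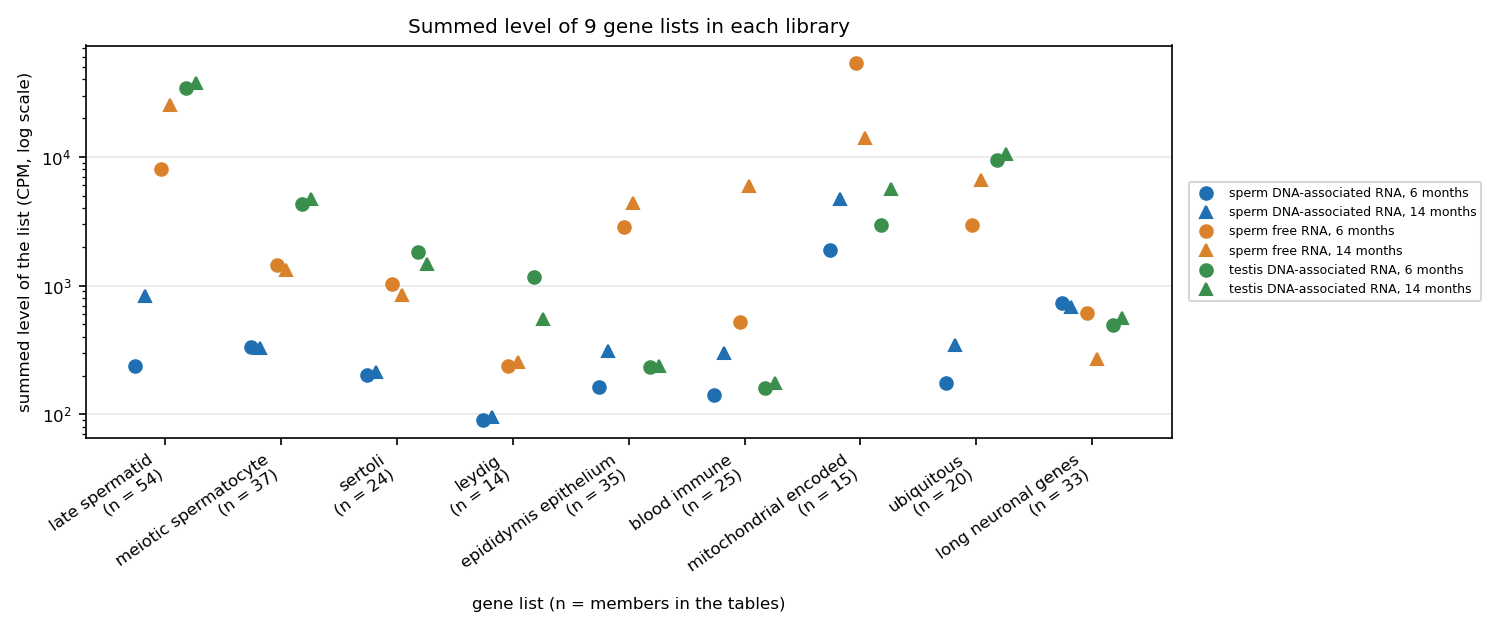
Summed level of 9 gene lists (CPM, log axis) in each of the 6 libraries, with circles for 6 months and triangles for 14 months. Late spermatid genes sum to 236.1 and 834.2 CPM in sperm DNA-associated RNA and to 34450 and 37510 CPM in testis, and long neuronal genes lie between 267.7 and 734.4 CPM in all libraries.

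The third comparison asks what differs between 6 and 14 months. Over the kinds of RNA together very few genes passed. Within kinds there is 1 library per age and no test. Haemoglobin transcripts stood higher at 14 months in all 3 kinds, and late spermatid transcripts mostly in the sperm fractions. Leydig cell transcripts stood lower at 14 months in testis. Both sperm fractions come from TRIzol extraction of sperm, so agreement between them is not shown to be independent evidence on age. The sperm free libraries differed most between ages.

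By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 genes rose and 0 fell with age over the 3 kinds, and DESeq2 called 100. Of 34355 tested genes 973 had an unadjusted edgeR p under 0.05, a smaller share than chance alone gives at that threshold. The 2 genes that rose are processed pseudogenes outside the naming rule and are named here after their values were seen. AC161207.2 had a log2 fold change of 8.65 (SE 0.67, edgeR adjusted p = 0.038), with 0.145 and 38.5 CPM in sperm free and 0.215 and 49.4 CPM in testis DNA-associated RNA at 6 and 14 months. Rpl34-ps1 (chromosome 6, 71124589 to 71125001), a copy of a ribosomal protein gene, had 8.16 (SE 0.69, edgeR adjusted p = 0.039). With library totals 0 genes passed by edgeR, with 503 at an unadjusted p under 0.05, again a smaller share than chance gives.

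By CPM from library totals, the genes selected by the naming rule moved the same way in all 3 kinds. None passed, with edgeR adjusted p of 0.73 or 0.74. The log2 fold changes use TMM, and with it the direction within a kind was not checked. It can differ in sperm free RNA, whose TMM factors were 1.34 and 0.511 at 6 and 14 months. Hba-a2 had a log2 fold change of 5.31 (SE 1.24) and Hbb-bs 4.69 (SE 1.23). Others with higher levels at 14 months were Ptchd3 (2.30, SE 0.62), the sialyltransferase gene St6galnac1 (2.19, SE 0.43), the axonemal gene Tcte3 (2.03, SE 0.58), the ribosomal protein gene Rps18 (1.80), Iqcf4 (1.70), Rtl6 (1.60) and Lyzl4os (1.55), the last an antisense RNA. With lower levels were Wdr37 (-2.40, SE 0.64), Rbm8a2 (-1.97), the vomeronasal receptor gene Vmn1r66 (-1.70), Cd300lg (-1.24), Klhl31 (-0.97), Olfr1352 (-0.96), Tchh (-0.54), Sv2c (-0.52) and Fam205a4 (-0.38).

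No list member passed for age, over all genes or adjusted over the list alone. With the preset correlation camera placed 10 lists higher at 14 months, led by late spermatid (median 1.51, camera adjusted p = 3.49e-27), blood and immune (0.98, 1.13e-07), ubiquitous (0.79, 9.8e-07) and epididymal genes (0.92, 3.53e-06), followed by non-coding machinery (0.89, 0.00275), senescence (0.79, 0.00346), peritubular (0.51, 0.0213), R-loop (0.35, 0.0239), meiotic (0.16, 0.028) and Sertoli genes (0.34, 0.0434). Each had an adjusted p = 0.651 with an estimated correlation, except Sertoli genes with 0.71. The preset adjusted p was 0.182 for spermatogonial (median 0.30), 0.367 for Leydig (0.26), 0.0662 for mitochondrial (0.62) and telomere (0.29), 0.546 for imprinted (0.17), 0.854 for nuclear long non-coding (-0.06) and 0.367 for long neuronal genes, whose median was 0.04, mean -0.17 and direction down. With library totals the calls were lost for R-loop (camera adjusted p = 0.269), meiotic (0.0639) and Sertoli genes (0.242), and the medians of 9 lists turned negative: meiotic, spermatogonial, Sertoli, Leydig, peritubular, R-loop, telomere, imprinted and long neuronal genes.

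In testis DNA-associated RNA, Leydig genes had a median log2 ratio of -0.90 between 14 and 6 months (-0.96 with library totals), below all 10000 matched random lists, of which 95% lay between -0.07 and 0.21. Insl3 (chromosome 8, 71689252 to 71690577) went from 336.5 to 81.7 CPM (log2 ratio -1.97, counting interval -2.02 to -1.92). The steroid synthesis genes Cyp17a1 and Cyp11a1 went from 195.6 to 71.6 and from 108.7 to 55.0 CPM, while Scarb1 was at 133.8 and 124.4 CPM. Other cell-type lists differed less: Sertoli genes had -0.09 (percentile 0.26) and peritubular and endothelial genes -0.16 (0.37), late spermatid genes 0.21 (99.97) and meiotic genes 0.20 (99.62). The haemoglobin genes Hba-a2 and Hbb-bs went from 3.91 to 20.1 and from 9.06 to 30.5 CPM, and Hba-a1 from 8.36 to 13.8 CPM. The blood and immune list as a whole went the other way, with a median of -0.14 (percentile 1.53). Its member Cd74 went from 13.5 to 7.68 CPM. Mitochondrial genes had a median of 0.73, above all random lists, with mt-Rnr2 at 767 and 2027 CPM. Non-coding machinery genes had -0.44, below all random lists, with Rn7sk at 8821 and 6334 CPM and Rnu1a1 at 585.1 and 361.9 CPM. Of 12237 genes considered, 215 were at least 2-fold higher and 215 lower at 14 months. Among the largest differences were Bfsp1, a lens filament gene (2.05 and 34.7 CPM), Cpne7 (1.44 and 26.9 CPM) and mt-Atp8 (4.13 and 31.4 CPM), and with lower levels Rd3 (38.9 and 0.238 CPM), the taste receptor gene Tas1r1 (26.9 and 0.346 CPM) and Kpna2, a nuclear import factor (245 and 10.4 CPM).

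In sperm DNA-associated RNA 163 of 5962 genes were at least 2-fold higher and 34 lower at 14 months. Mitochondrial (median log2 ratio 1.30), late spermatid (1.12), non-coding machinery (1.12), ubiquitous (0.60) and epididymal genes (0.57) lay above all random lists, and each of these medians was at least 0.53 with library totals. Prm2 went from 10.4 to 99.7 CPM (log2 ratio 3.21, counting interval 2.89 to 3.53), Tnp2 from 4.62 to 60.8 CPM, Rn7sk from 22.4 to 184.5 CPM and Rn7s1 from 218.5 to 1430.0 CPM. Hba-a2 went from 0.649 to 53.2 CPM and Hbb-bs from 1.36 to 52.9 CPM. Lower at 14 months were Wdr37 (681.1 and 47.3 CPM), the ribosomal protein gene Rpl7 (145.8 and 6.85 CPM) and Mbnl1, a splicing factor (73.0 and 21.3 CPM).

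In sperm free RNA 7384 of 14184 genes were at least 2-fold higher and 1526 lower at 14 months with TMM, but 1086 higher and 4181 lower with library totals, so the split follows the scaling. Late spermatid and blood and immune genes had medians of 2.76 and 2.63 (1.41 and 1.28 with library totals), above all random lists, as did senescence and inflammation genes (1.41, and 0.26 with library totals). Meiotic genes lay near the bottom of the random lists (0.00, percentile 0.01, and -0.97 with library totals). Hba-a2 went from 45.8 to 1917 CPM and Hbb-bs from 51.7 to 1820.0 CPM. The log2 ratio of Hba-a2 was 6.73 with TMM (counting interval 6.65 to 6.82) and 5.36 with library totals. Cxcl2, a neutrophil-attracting chemokine, went from 12.7 to 115.1 CPM, Prg4, the lubricant proteoglycan, from 11.4 to 108.9 CPM, and the lipoxygenase gene Alox15 from 8.62 to 65.7 CPM. Mitochondrial genes had a median of -0.56 (-1.94 with library totals), below all random lists, with mt-Rnr2 at 27350 and 6056 CPM and mt-Rnr1 at 10380 and 3049 CPM. Among the largest differences downwards were Olfr639 (195.6 and 4.67 CPM), Olfr46 (432.8 and 10.9 CPM) and Xkrx (1142 and 32.5 CPM).

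**Figure D4:**
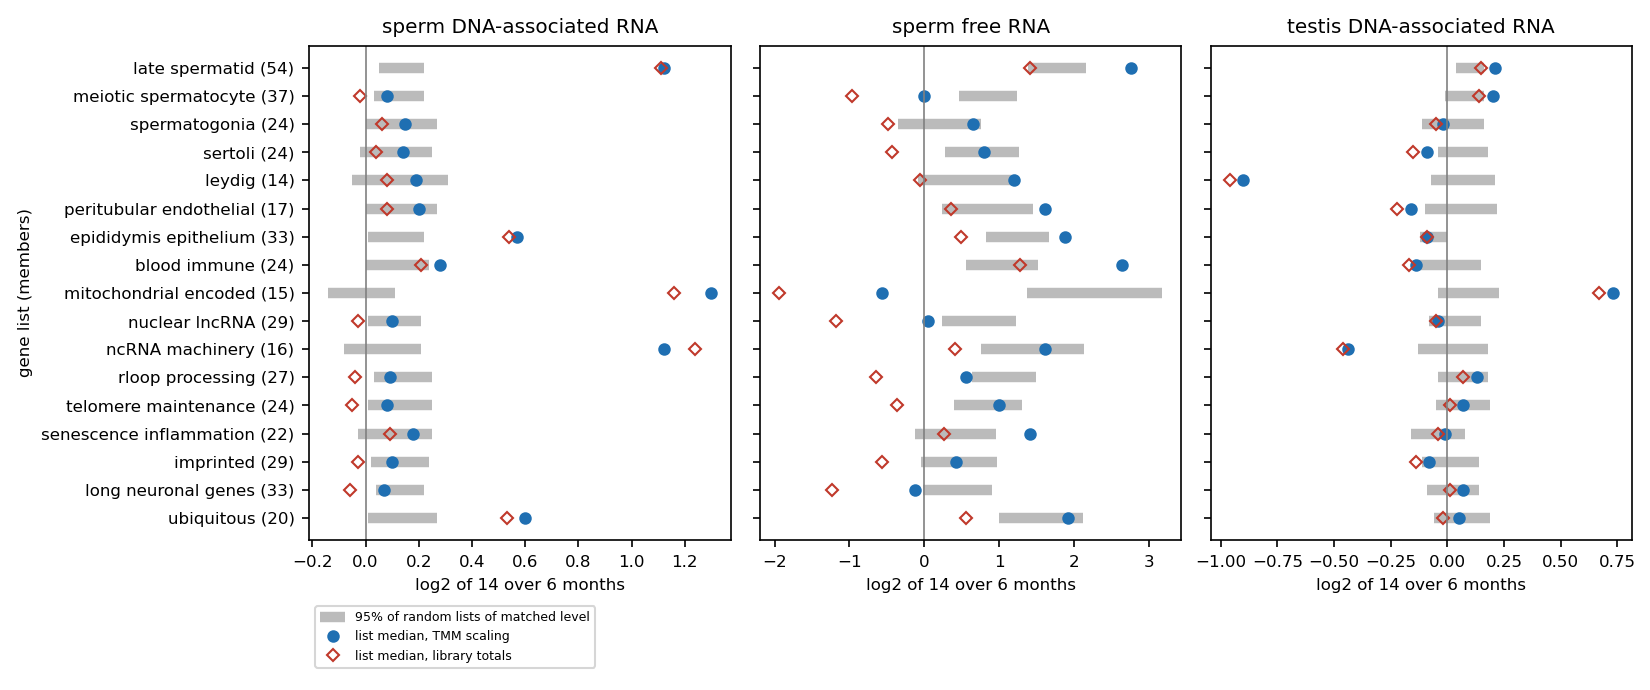
Median log2 ratio of 14 over 6 months of each gene list within each kind of RNA, with TMM (points) and library totals (diamonds), over grey bars that span 95% of random lists of matched level. Leydig genes lie at -0.90 in testis, and mitochondrial genes at 1.30, -0.56 and 0.73 in sperm DNA-associated, sperm free and testis RNA.

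The deposited list of chromosome ends covers 22 chromosomes of mm10, 19 of which carry 6 to 16 copies of the telomere repeat TTAGGG in their last 100 bases. Of 8 nuclear RefSeq genes in the listed windows, 1 is in the tables, and 0 genes of the last windows are. Telomeric repeat RNA itself was not analysed here, since that file holds no value per sample.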

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

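Of the tests in this part, those of RNA in proportion to testis expression, of carry-over of whole material and of a smaller genomic component were chosen after the results were seen. For the first, a bound of 4 times was also replaced, once its value was known, by 1 of 10 times below the ratio in testis, since 4 is far below what proportion to testis would give; the first bound would have kept that explanation. Mitochondrially encoded genes moved in opposite ways with age in the sperm fractions. Their summed level at 14 months was 0.265 times that at 6 months in sperm free RNA, from 53380 to 14120 CPM. The size of this fall follows the scaling: the list's median log2 ratio was -1.94 with library totals and -0.56 with TMM, with mt-Co1 at 0.13 with TMM. It was 2.49 times that at 6 months in sperm DNA-associated RNA and 1.93 times in testis DNA-associated RNA. The difference between the kinds of RNA was not tested, because each rests on 1 library per age.

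The sperm DNA-associated libraries had a flat profile: the SD of log2 TPM over autosomal protein-coding genes was 1.21 at both ages. It was 1.84 and 1.8 in sperm free RNA, also below testis, with 2.96 and 3.19. Genomic DNA would bring X-linked genes, which male cells hold in fewer copies, to a lower level than autosomal ones. That ratio was 0.565 at 6 months (0.431 to 0.653) and 0.555 at 14 months (0.482 to 0.672). In testis it was 0.688 (0.448 to 0.893) and 1.191 (0.745 to 1.887), so the 6-month intervals of the 2 tissues overlap. Olfactory receptor genes in the sperm DNA-associated libraries lay at 0.771 and 0.738 of other autosomal genes, just under the range set for DNA. A DNA component can therefore not be told apart from RNA here. RNA in proportion to testis levels would set the 10% of genes highest in testis over those near 0 as in testis, 1880-fold and 5440.0-fold. The ratio was 4.05 and 5.82, a far flatter profile over these genes. Both gene sets were picked by level in the testis libraries themselves, which widens the testis ratios. The bound was also chosen with the value known, so no conclusion on this explanation as the whole source is drawn. A mixture of sources, and the fraction itself, DNA-associated RNA of sperm, stay open and untested.

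The 6-month sperm free library held silent genes and satellite-related models that the 14-month one nearly lacked (5.31% and 0.0405% of reads for the models). Carry-over of the DNA-associated material as a whole needs the same free to DNA-associated ratio for both. The ratio was 0.371 for silent genes and 0.105 for the models, 3.52 times apart, which argues against such carry-over. Genomic DNA with few satellite reads could give X-linked genes a low level, and the X to autosome ratio was 0.756 with an interval of 0.555 to 0.945, too wide to decide. Olfactory receptor genes lay at 0.992 of other autosomal genes (0.926 to 1.053), within the range set for DNA in the sperm DNA-associated libraries. That value was not part of the test set for this library, and DNA stays open. Age, the design's own difference between these libraries, stays open and untested.

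Haemoglobin transcripts stood at 12.9 to 41.8 times their 6-month level in the 14-month sperm free library. Of these genes, Hba-a2 also went from 0.649 CPM, on 5 reads, to 53.2 CPM in sperm DNA-associated RNA. In the separate testis libraries Hba-a2, which shares reads with a near-identical copy, went from 3.91 to 20.1 CPM. There Hbb-bs went from 9.06 to 30.5 CPM, and Hba-a1 (8.36 and 13.8 CPM) and Hbb-bt (0.8115 and 1.265 CPM) differed less. Blood in the sperm preparation leaves the testis values unexplained. For the sperm free library such blood may be a source, and other red-cell genes fixed for the test had a median ratio of 1.51, with 4.53 for Alas2 and 1.29 for Slc4a1, with a ratio of 4 needed and one under 1.5 against it, which leaves blood open. A smaller genomic component alone would raise haemoglobin and late spermatid genes alike. The haemoglobin median was 28.3 against 2.69 for late spermatid genes, 10.5 times as much, which argues against it. A change of the animals with age was not tested apart from these.

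The age contrast called 2 genes. Of the 10 splits of the 6 libraries into 3 and 3, the real one included, 3 called at least as many, and the highest other count was 15371. With 10 splits a share under 0.05 cannot be reached. Both splits with 15371 calls are 1 comparison with its sign turned: they set 1 sperm free library against the other, with the spread taken from the other kinds, so this count is no test. It points only to a structure of the samples, the sperm free pair being less alike (Pearson's r 0.87) than the others (0.96 and 0.99).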

How the results depend on the processing

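The alternative without satellite-related models was chosen after seeing the data. No paired analysis was possible because the table columns carry no replicate numbers, so that rep1 and rep2 could not be matched between groups. The age term already compares the kinds of RNA within each age, and without it 9837 and 22100 genes passed for the fraction and tissue comparisons. Also not run were quantile normalization and other pseudocounts, since the values are counts, and other scales or thresholds for telomeric RNA, since that file holds no sample values. The cause was not tested for the changes below, except that stricter filters and left-out libraries leave fewer genes or samples.

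The count of 10084 genes for sperm DNA-associated against free RNA was 5482 with library totals, 6075 with only the groups compared and 15676 with each table as its own library, and ranged from 181 to 24426 over left-out libraries. Leaving out the 6-month DNA-associated (1782), 14-month DNA-associated (181) or 6-month free library (24426) moved it by over 1.5 times, and a lone library is then assumed to vary like the others. Of the genes called, 9821 were called the same way without the 6-month free library. The count of 22295 for testis against sperm DNA-associated RNA stayed within 1.5 times under the other settings and ranged from 5589 to 28874 over left-out libraries, with 14728 and 5589 without the 6-month and 14-month sperm DNA-associated and 9851 and 12719 without the testis libraries.

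The count of 2 for age was 1 with DESeq2 size factors, 1 without satellite-related models, 100 by DESeq2, 50 with no filter and 21 with each table as its own library. By edgeR, library totals, the stricter filter and transcripts gave 503, 442 and 1176 at an unadjusted p under 0.05, each below the chance share. After adjustment the count was 0 in each, against 100 by DESeq2. Over left-out libraries it ranged from 3 to 174: 159 and 174 without the sperm DNA-associated libraries, and 21 and 48 without the 6-month and 14-month free ones. Counts within kinds at the stricter filter were 81 in sperm DNA-associated (197 before), 2164 in sperm free (8910 before; 5267 with library totals) and 86 in testis RNA (430 before). At 5 CPM, 17334, 15355 and 13554 genes were detected on average in sperm DNA-associated, sperm free and testis RNA, against 34623, 25182 and 21472 at 1 CPM. Of the 31 list calls, 0 held with an estimated correlation.

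Of 178 results for named genes, 58 kept direction and call under all alternatives run, 111 changed their side of the threshold or their size under some, and 9 turned direction. Leaving out the 14-month sperm DNA-associated library ended 72 calls and the 6-month one 53, while library totals ended 14. None of the 9 passed the test before. For sperm DNA-associated against free RNA, Smchd1 (-0.23) had log2 fold changes of 0.20 with DESeq2 size factors and with the DESeq2 test, 0.63 with library totals, 0.91 with the stricter filter, 0.29 with only the groups compared and -0.36 to 0.63 over left-out libraries. Auts2 (-0.94) had 0.23 with the stricter filter, and Kcnq1ot1 (0.36) -0.38 to 2.02 over left-out libraries. For testis against sperm, Auts2 (0.39) had -0.66 with library totals, -1.21 with the stricter filter and -0.37 to 0.39 over left-out libraries. Col3a1 (1.30) had -0.32 with the stricter filter and -0.22 to 1.21 over left-out libraries, Hba-a2 (2.01) -0.17 without the age term and -1.10 to 2.87, Hbb-bs (2.51) -0.70 to 3.23, Rn18s-rs5 (-0.21) 0.24 with no filter and -2.93 to 0.24, and Smchd1 (-0.51) 0.02 with no filter. In the simulation, which left out the real differences between the kinds of RNA, 0% of changes of log2 1 were recovered. Depth alone was not varied.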

Other observations

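The values in this part come from no planned test. Long neuronal genes, which span long stretches of genome, had a median level of 19.7 and 20.3 CPM in sperm DNA-associated RNA at 6 and 14 months, 13.5 and 4.05 CPM in sperm free RNA, and 9.85 and 8.52 CPM in testis DNA-associated RNA. Imprinted genes summed to 1445 and 1268 CPM in sperm DNA-associated, 1568 and 503.6 CPM in sperm free and 674.9 and 679 CPM in testis DNA-associated RNA. Kcnq1ot1 alone gave 1052 and 894.5 CPM in sperm DNA-associated and 1035 and 134.6 CPM in sperm free RNA. Lars2, a mitochondrial leucyl-tRNA synthetase gene singled out after its values were seen, took 0.655% and 3.98% of sperm DNA-associated, 1.81% and 1.99% of sperm free and 0.07% and 0.036% of testis DNA-associated reads.

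Epididymal epithelium genes had a median level of 30.3 and 69.1 CPM in sperm free RNA, 2.18 and 4.8 CPM in sperm DNA-associated RNA and 0.176 and 0.0865 CPM in testis. Blood and immune genes summed to 520.7 and 5979 CPM in sperm free RNA. Of this, the haemoglobin genes Hba-a2, Hbb-bs and Hba-a1 gave 45.8, 51.7 and 65.6 CPM at 6 months. At 14 months they gave 1917, 1820 and 1396 CPM, so most of the 14-month sum was haemoglobin. The only gene of the nuclear chromosome-end windows that is in the tables, the pseudogene V1rg10 on chromosome 5, had 12.2 and 12.1 estimated reads in sperm DNA-associated, 4.4 and 0 in sperm free and 3.0 and 0 in testis libraries, named after its values were seen.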
